A study of Mus musculus with 12 samples.

How the data were processed

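ATAC-seq, which marks open chromatin by the insertion of Tn5 transposase, was measured in 12 libraries of mouse embryoid bodies grown from embryonic stem cells under mesodermal conditions. Stem cells had been kept on irradiated fibroblast feeders, which were removed by plating before differentiation. Groups were taken from the labels: Foxk1 knockout (KO) at days 3, 5 and 10, the iHA-Foxk1 line without doxycycline at days 3 and 5, and libraries labelled Control at day 10, with 2 libraries in each of the 6 groups. The iHA-Foxk1 libraries (days 3 and 5) and the Control libraries (day 10) served as the control arm of their own day. Nothing in the labels says that the 2 libraries of a group came from separate differentiations, so p-values measure the spread between these libraries, which may be technical.

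Per the submitters' processing notes, the authors used Bowtie2 2.2.4, MACS2 (version not given in the sources used here) and the mm10 build. The deposited files are 1 list of peak summits per library, so replicates were not pooled before peak calling. The deposited score of each summit is a −log10 value of a p-value or q-value, as MACS2 writes it, and which of the pair it is was not given in the sources used here. Smallest scores were close to 1.30, the −log10 of 0.05, in the libraries of days 3 and 5, and between 1.78 and 1.85 at day 10. Peak names at days 3 and 5 carry a duplicate-removal tag that the day 10 names lack, so day 10 and a change in processing cannot be told apart. Peak names inside both lists labelled KO day 5 carry the tag D7, while the labels give day 5. The labels were followed, and every comparison with these libraries is open to a difference in day.

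Each list holds 1 summit per peak, no read counts and no peak widths. Read depth behind each library is therefore unknown, and the number of summits was the only depth-like value, from 4028 to 59006 on chromosomes 1 to 19 and X. Summits on Y, the mitochondrial genome and contigs were left out of the main comparisons. No list of regions prone to artefact signal was used to filter the summits. Scores were used only to rank summits within their own list. For each comparison every library was reduced to its N highest-scoring summits, N being the length of the shortest list compared: 53456 at day 3, 14519 at day 5 and for day 3 against day 5, and 4028 at day 10 and over all 12 libraries. Shares of summits per chromosome were the exception and were taken over full lists. Summits of the libraries compared were merged into regions by single linkage at 250 bp. A region was KO-only with a summit in both KO libraries and neither control library, and control-only in the reverse case, and the same rule was used between days. Counts were set beside those of the other splits of the same 4 libraries. Regions found in both libraries of at least 1 arm, called reproducible, were the background of all enrichment tests.

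The annotation used here was a RefSeq gene table of GRCm38.p6, the assembly of mm10, with the start and end of each gene but neither strand, exons nor sequence. The planned transcription start site was replaced by the nearer of the 2 ends of a protein-coding gene (21631 genes on these chromosomes), within 100 kb. The planned classes became within 1 kb of a gene end, inside a gene body, and elsewhere. The planned motif analysis was not run, because it needs sequence. All 340 symbols of the 18 gene lists were matched. The lists were pluripotency, epiblast, primitive streak and nascent mesoderm, cardiac progenitor regulators, cardiomyocyte contractile, endothelial, haematopoietic, paraxial mesoderm and skeletal muscle, neural, endoderm, Wnt ligands, Wnt targets and regulators, Hox genes, fibroblast (feeder), glycolysis, autophagy, cell cycle and housekeeping. Groups, lists, the main tests and most other settings were fixed before the data were examined. Added later were random lists, absence within 1 kb, odds ratios of lists under other merging, bins, absence rules and splits, lists without a day, tests of a genotype difference between days, and leaving out libraries for chromosomes and for day 10 against earlier days.

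Values per library were compared by two-sided exact permutation of the genotype within days (216 arrangements, smallest p 0.00926), with Benjamini-Hochberg adjustment over 18 lists, 3 annotation classes or 20 chromosomes. With 2 against 2 libraries inside a day no p under 0.333 is possible, so no permutation test was made within a day. Agreement of replicates was tested one-sided over 27 arrangements (smallest p 0.037), and list shares of day 3 against day 5 two-sided over 36 arrangements within genotypes (smallest p 0.0556). Lists were also tested across regions by two-sided Fisher's exact tests, adjusted over 108 tests of lists, days and directions. Such a test takes regions as units and compares these 4 libraries, not cultures in general. For lists below 0.05 before adjustment and with a raised share of called regions, 10000 random gene lists with the same number of regions per gene were drawn as well.

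Named genes followed a rule: Foxk1 and Foxk2; per day and direction the genes nearest to the 10 best-ranked regions with no summit of any score within 250 bp in the other genotype, passing over predicted genes; up to 4 members per list with a called region; and 5 regions per direction for comparisons of days. Genes named outside it are marked as chosen after their values were seen, and a few members that the rule names are not reported here. Alternatives were all summits or N divided by 2, merging at 100 or 500 bp, fixed 1 kb bins, absence judged on full lists, other gene distances, pairing by replicate number, and each library left out in turn.

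Region calling was tested on simulated lists with 100 changed regions per day and shift, drawn from regions in all 4 libraries. A shift of 4 in log strength was recovered in 99% (day 3, 82081 regions), 96% (day 5, 23232 regions) and 95% (day 10, 7183 regions), and a shift of 1 in 30%, 32% and 31%. All simulated libraries had the same noise, so that lists of unequal quality, as at day 5, were not covered. In 200 simulations without an effect, 2% of permutation p-values fell under 0.05. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.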

Results

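Open chromatin was mapped in embryoid bodies that lacked Foxk1, a forkhead transcription factor, and in control embryoid bodies at days 3, 5 and 10 of mesodermal differentiation. The design asks which regions differ in accessibility when Foxk1 is missing, at the stages when mesoderm and then cardiac progenitors form. At day 3 the KO libraries held 59006 and 53456 summits and the iHA-Foxk1 libraries 53473 and 54100. At day 5 there were 48391 and 42129 in the KO and 14519 and 34040 in iHA-Foxk1, so that control replicate 1 had the shortest list of these days. At day 10 the KO lists held 4028 and 4755 summits and the Control lists 10548 and 7764. Mean summit numbers in the KO were 1.05, 1.86 and 0.48 times those of the controls at days 3, 5 and 10. Over all days the log10 number of summits differed by 0.00366 (KO minus control, n = 6 against 6, two-sided exact permutation p = 1).

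**Figure D1:**
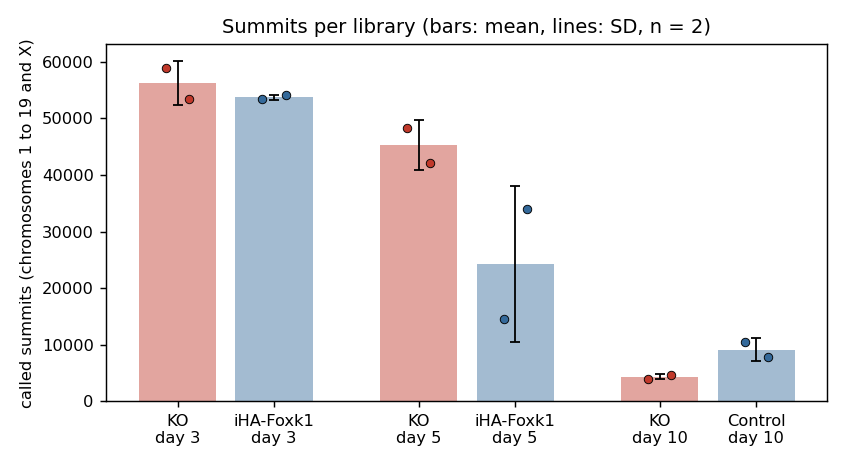
Number of called summits on chromosomes 1 to 19 and X (vertical axis) in each group (horizontal axis). Points are libraries, bars the group mean and lines the SD (n = 2); lists were longest at day 3 (53456 to 59006) and shortest at day 10 (4028 to 10548).

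Libraries of one genotype shared more summits on average than libraries of different genotypes. At day 3, between 75.8% and 79.9% of the compared summits had a partner within 250 bp in the same genotype, against 69.8% to 71% across genotypes. At day 5 the values were 65.6% to 85.5% and 57.9% to 76.9%, and the control libraries (65.6%) shared fewer summits than iHA-Foxk1 replicate 2 shared with the KO libraries (76.9% and 75.3%). At day 10 the values were 62% to 70.1% and 58.9% to 61.9%. The mean difference was 7.11 percentage points (7.39, 8.3 and 5.64 at days 3, 5 and 10, one-sided exact permutation p = 0.037, the smallest p of the design).

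At the targeted gene, Foxk1 (gene 17425, chromosome 5, 142401497 to 142462015 in mm10), summits persisted in the libraries labelled KO. A region at the gene's lower end (142401416 to 142401682) held a summit in 4 of 4 KO and 3 of 4 control libraries of days 3 and 5. Inside the gene, 142440490 to 142440666 held one in 4 of 4 and 4 of 4, and 142463884 to 142463967, beyond the other end, likewise. Other regions inside the gene held summits in 1 genotype alone: 142451792 to 142451990 in 2 and 142451531 in 1 control library, 142415528 in 1 control library, and 142457474 to 142457559 in 2 KO libraries. Accessibility of this locus does not test the knockout, since the deleted part is not stated in the labels used here and open chromatin can remain without a protein. Foxk2, the closest relative of Foxk1, is gene 68837 (chromosome 11, 121259987 to 121309900). The region 121259771 to 121259995 at its lower end held a summit in 4 of 4 KO and 4 of 4 control libraries of days 3 and 5. At day 10 both Control libraries and neither KO library had one there, but the KO lists were shorter (4028 and 4755 against 10548 and 7764 summits).

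At day 3, regions near genes of the primitive streak and nascent mesoderm were called in the control alone more often than other regions. Of 81 reproducible regions near this list, 25 (30.9%) were control-only, against 9.56% of other regions (odds ratio 4.22, two-sided Fisher's exact test, adjusted p = 6.4e-06 over 108 tests). They lay near 14 of the 19 members with a region. Of the 25, 24 had no KO summit of any score and 19 had none within 1 kb. The best-ranked were near Mixl1, a homeobox factor of the streak (chromosome 1, 180697351 to 180697417, 350 bp from the gene), Gsc, the homeobox gene goosecoid (chromosome 12, 104486405 to 104486421, 13177 bp), Aplnr, the apelin receptor (chromosome 2, 85160735 to 85160762, 20825 bp), and Snai1, a repressor active in epithelial to mesenchymal transition (chromosome 2, 167543356 to 167543431, 579 bp). Gsc alone had 5 control-only regions, counted after its values were seen. In the KO, 11 of the 81 regions (13.6%) were KO-only (odds ratio 1.46, Fisher's exact test, adjusted p = 0.934), near Eomes, Mixl1, Dll1 and Aplnr among 10 genes. All but Sp5 of these 10 genes, namely Eomes, Mixl1, Dll1, Aplnr, Nodal, Snai1, Gsc, Fgf8 and Lhx1, had control-only regions as well (9 genes, named after their values were seen), so that each genotype had summits of its own at different positions of the same genes. In 10000 random gene lists with as many regions per gene, the median control-only share was 11.1% and the share of this list was never reached. Among the other splits of the 4 libraries, at most 3 regions of the list were called. With N divided by 2 the odds ratio was 2.3 and the call ended (Fisher's exact test, adjusted p = 0.735), and it was 2.64 and 2.75 without iHA-Foxk1 replicates 1 and 2.

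**Figure D2:**
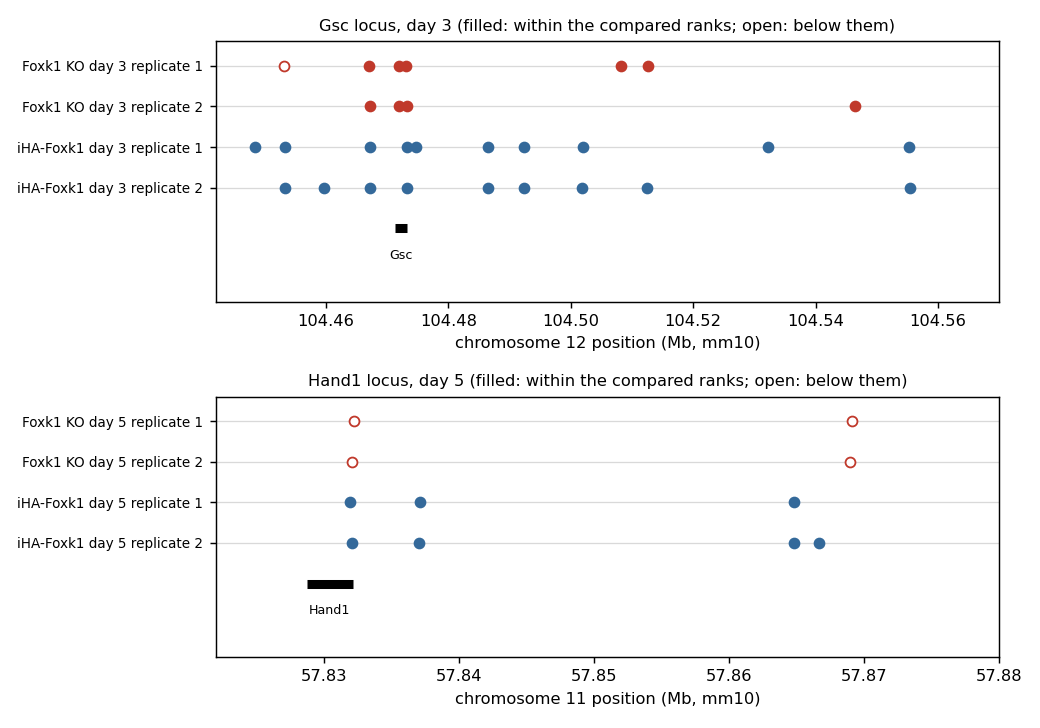
Called summits at Gsc at day 3 and at Hand1 at day 5, by library (vertical axis) and mm10 position in Mb (horizontal axis); red is KO, blue iHA-Foxk1, black bars are genes, filled points lie within the compared ranks (53456 and 14519 per library) and open points below them. Of the 5 control-only regions of Gsc, 4 lay at position 104486405 or higher.

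Other lists did not pass at day 3 by Fisher's exact test. Of 126 regions near Wnt targets and regulators, 13 were control-only, led by Axin2, Myc, Fzd7 and Lef1, and 8 KO-only, led by Lef1, Fzd8, Tcf7l2 and Tcf7 (exact test, adjusted p = 1 and 0.934). Of 65 regions near Wnt ligands, 3 were control-only (Wnt7a, Wnt2b, Wnt3) and 7 KO-only, led by Wnt2b, Wnt2, Wnt10b and Wnt5a (both with adjusted p of at least 0.934). Cardiac progenitor regulators had 13 control-only regions of 90, led by Fgf10, Smyd1, Hand2 and Mef2c, and 7 KO-only, led by Tbx20, Isl1, Gata6 and Nkx2-5 (exact test, adjusted p = 0.934 and 1). Near Hox genes, 1 of 67 regions was control-only (Hoxd4) and 10 were KO-only, among them regions near Hoxb9, Hoxb13 and Hoxa10, and the low control-only share fell short after adjustment (exact p = 0.0198, adjusted p = 0.322). Near pluripotency genes, 10 of 80 regions were KO-only (led by Klf2, Tbx3, Klf5 and Dppa3) and 8 control-only (Prdm14, Zfp42 and Klf5), with an adjusted p of 1 by the exact test for both.

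Over the genome, day 3 had 5092 KO-only and 5012 control-only regions among 52246 reproducible ones, while the other splits of the libraries gave 1138 to 1308. Of these, 5050 and 4648 had no summit of any score in the other genotype. Gene ends were rare among them: 6.95% of KO-only and 5.91% of control-only regions lay within 1 kb of one, against 34.6% of regions in all 4 libraries. Best-ranked KO-only regions lay near Col19a1, Tcstv3, Atp6v1h, Slc35f5, Tmem267, Gria4, Trim30d, Il17a, Fbxo30 and Trim12a. Control-only ones lay near Col19a1, Slc35f5, Defa21, Smco2, Gria4, Tlk2, Grxcr1, Rab28, Cldn12 and Fbxo30. Col19a1, Slc35f5, Gria4 and Fbxo30 stood in both, and a summit of the other genotype lay within 1 kb of 5 of the 10 KO-only and 8 of the 10 control-only regions. The Col19a1 regions lay between genes, 26342 bp (KO-only) and 25392 bp (control-only) from that gene. Whether best-ranked regions such as these carry artefact signal was not tested. Over all calls, 4378 KO-only and 4011 control-only regions had no summit of the other genotype within 1 kb. The rule asks for every library of an arm, so leaving out a library loosened it: KO-only counts were 11294 and 10898 without KO replicates 1 and 2 and 8029 and 8244 without iHA-Foxk1 replicates 1 and 2, and control-only counts 11816 and 12216 without the latter. With N divided by 2 there were 2520 KO-only and 2512 control-only regions.

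**Figure D3:**
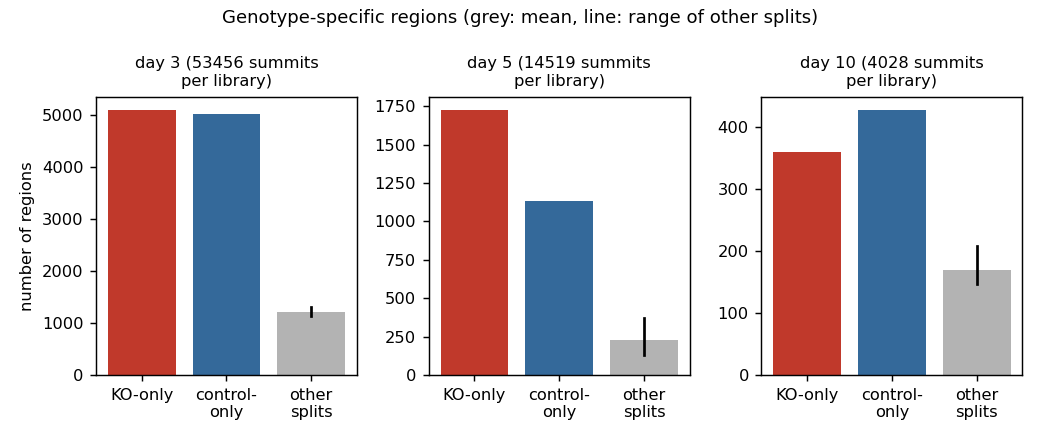
Number of KO-only (red) and control-only (blue) regions at each day (vertical axis, separate scale per day), with the mean (grey) and range (line) of the same counts under the other splits of the 4 libraries. Both counts lay above that range at each day, for example 5092 and 5012 against 1138 to 1308 at day 3.

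At day 5, control-only regions gathered near regulators of cardiac progenitors. Of 25 reproducible regions near this list, 12 (48%) were control-only, against 7.88% of other regions, and none was KO-only (odds ratio 10.8, two-sided Fisher's exact test, adjusted p = 6.4e-06 over 108 tests). They lay near 8 genes. The best-ranked were near Hand1, a factor of early heart and lateral mesoderm (chromosome 11, 57864846 to 57864847, 32699 bp from the gene), Gata6, a zinc-finger factor of heart and endoderm (chromosome 18, 11052467 to 11052521, 16 bp), Fgf10, a growth factor of the second heart field (chromosome 13, 118759125 to 118759133, 33444 bp), and Isl1, a marker of the same field (chromosome 13, 116201699 to 116201729, 96556 bp). Random gene lists had a median of 16% and none of the 10000 reached 48%. Of the 12 regions, 8 had a KO summit below the compared ranks and 4 had none at any score (near Hand1, Gata5 and Bmp2). A KO summit below the compared ranks has a lower place in its own list, which alone does not show a loss of accessibility. Under the other splits up to 3 regions were called, with an odds ratio of up to 7.25 (3 of 16 regions in KO replicate 1 and iHA-Foxk1 replicate 2 alone, exact p = 0.0123). With all summits the odds ratio was 4.64 (exact test, adjusted p = 0.135) and with N divided by 2 it was 8.58 (adjusted p = 0.734), which ended the call, while merging at 100 bp gave 19.4, absence judged on full lists 12.1 (adjusted p = 0.0316, exact test) and absence within 1 kb 16.6. Without iHA-Foxk1 replicates 1 and 2 it was 2.46 and 4.1 (exact test, adjusted p = 0.00175 and 0.00327), and peak names in both KO lists carry the tag D7.

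Of the further lists with control-only regions at day 5, 6 were under 0.05 before adjustment and none after it. Hox genes had 3 of 5 regions (Hoxb1, Hoxd1 and Hoxc6, Fisher's exact p = 0.00444, adjusted p = 0.16), and contractile genes of cardiomyocytes 3 of 9 (Tnni1, Actc1 and Myl4, adjusted p = 0.395). Endothelial genes had 3 of 8 (Erg, Tie1 and Eng, exact test, adjusted p = 0.322), endoderm genes 4 of 12 near Cxcr4 and Cdx2 (adjusted p = 0.316), and streak genes 2 of 4 (Wnt3 and Lhx1, adjusted p = 0.408). Pluripotency genes had 4 of 14 (Lin28a, Sall4, Dppa4 and Nanog, exact test, adjusted p = 0.322). Fibroblast (feeder) genes, a marker of cells carried over from culture, had 2 of 5 (Loxl1 and Col1a2, exact p = 0.0537, adjusted p = 0.58). Without iHA-Foxk1 replicate 1, which also raised N to 34040, 5 of 108 tests passed in place of 2.

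In all, day 5 had 1725 KO-only and 1135 control-only regions among 14276 reproducible ones, against 133 to 371 under the other splits. Regions with no summit of any score in the other genotype numbered 1053 and 225, judged on full lists that were longer in the KO. Best-ranked KO-only regions lay near Col19a1, Kpna1, Tmem267, Zfp978, Atp6v1h, Ints13, Zfat, Impact, Srsf5 and Ddx42, and control-only ones near Col19a1, Ywhag, Zfat, Ints13, Rbpj, Ccdc47, Gpr19, Hand1, Tmem267 and Plxdc2. A summit of the other genotype lay within 1 kb of 7 of these 10 KO-only and 8 of these 10 control-only regions, and over all calls 940 KO-only and 166 control-only regions had none there. Using all summits gave 12889 KO-only and 700 control-only regions, as the longer KO lists would, and N divided by 2 gave 364 and 315. Without iHA-Foxk1 replicate 1 the counts were 8500 and 11737, without its replicate 2 they were 4165 and 5292, and KO-only counts were 3084 and 2883 without KO replicates 1 and 2.

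At day 10, control-only regions lay mostly at gene ends and KO-only regions mostly away from them. Gene ends made up 79.7% of the 428 control-only and 18.6% of the 360 KO-only regions, against 63.9% of the regions in all 4 libraries. The other splits gave 147 to 209 regions. Best-ranked control-only regions lay near Zfp825, Hey2, a transcriptional repressor downstream of Notch in ventricular muscle (chromosome 10, 30842828 to 30842896, 79 bp from the gene), Thnsl1, Snrpd2, Ndfip2, Psmc6, Cep97, Plaa, Recql and Idh1, and 8 of these 10 had no KO summit within 1 kb. KO-only ones lay near Ccr1, Nmi, Wwox, Tom1, Muc6, Def8, Zdhhc14, Gng4, Fbxo5 and Scaf8, and 3 of 10 had no control summit within 1 kb. No list passed (smallest Fisher's exact p = 0.0868, autophagy, KO-only), and few list members had a region: among them, Isl1, Bnip3, Cdkn2c and Actb were control-only and Zfp42, Smarcd3, Tcf7l2, Pkm, Pik3c3 and Atg7 KO-only. Only 88 KO-only regions had no control summit of any score, against 371 control-only regions with no KO summit, but full lists were longer in the Control libraries (10548 and 7764 against 4028 and 4755), so that these 2 counts are not comparable. All summits gave 111 and 2359 regions, and N divided by 2 gave 239 and 237. Without Control replicates 1 and 2 the counts were 560 and 592 KO-only and 1066 and 1045 control-only, and without KO replicates 1 and 2 they were 1312 and 1258 KO-only and 875 and 821 control-only.

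Over the 12 libraries, no list differed between genotypes after adjustment. Summits near streak genes were fewer in the KO at day 3 (11.8 ± 0.265 against 15.8 ± 0.397 per 10000 summits, SD, n = 2 each) and at day 5 (2.07 ± 0 against 6.89 ± 0.974). At day 10 they were 0 ± 0 and 1.24 ± 1.76. At N of 4028 a summit counts as 2.48 per 10000, so that list values of day 10 can rest on very few summits. The mean difference was −3.36 (two-sided exact permutation p = 0.0278, adjusted p = 0.5), with lower values in 4 of 4 KO libraries of days 3 and 5. Even the smallest possible p, in 1 list alone, would have given an adjusted 0.167. Without day 10 the difference was −4.42 (exact permutation p = 0.0556) and without day 5 it was −2.63 (exact permutation p = 0.167).

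Cardiac progenitor regulators had 9.99 ± 0.487 (KO) and 22.7 ± 4.87 (control) summits per 10000 at day 5, 16.4 ± 2.25 and 17.4 ± 0 at day 3, and 7.45 ± 0 and 3.72 ± 1.76 at day 10 (SD, n = 2, mean difference −3.35). The day 10 values again rest on very few summits. At day 5 most lists were lower in the KO: 16 of 18 in the mean and 10 with no overlap of the libraries (cardiac, streak, pluripotency, contractile, endothelial, endoderm, Wnt targets, Hox, fibroblast and glycolysis), where chance gives 16.7% for 1 list. At day 3, 8 lists were lower in the mean (2 with no overlap) and 10 higher (6 with no overlap), and at day 10, 5 were lower and 7 higher (2 with no overlap in each direction). Differences, KO minus control, for lists lower in the KO on average were −0.259 for pluripotency, −0.612 for epiblast, −0.94 for cardiomyocyte contractile, −0.921 for endothelial and −0.782 for haematopoietic genes. They were −0.255 for neural, −1.21 for endoderm, −0.301 for Wnt targets and regulators, −0.0482 for Hox, −0.867 for fibroblast (feeder), −2.14 for cell cycle and −1.67 for housekeeping genes. Differences were 0.156 for paraxial mesoderm and skeletal muscle, 0.599 for Wnt ligands, 0.129 for glycolysis and 2.28 for autophagy genes. The streak list was the only one of 18 under 0.05 before adjustment by exact permutation. Fibroblast (feeder) genes had 3.44 ± 0.974 summits per 10000 in the KO and 6.89 ± 0 in the control at day 5, lower in the KO like the cardiac and streak lists of that day, and 8.23 ± 0.265 against 7.39 ± 0.397 at day 3 (3.44 ± 0 against 3.79 ± 0.487 there at the N of day 5).

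**Figure D4:**
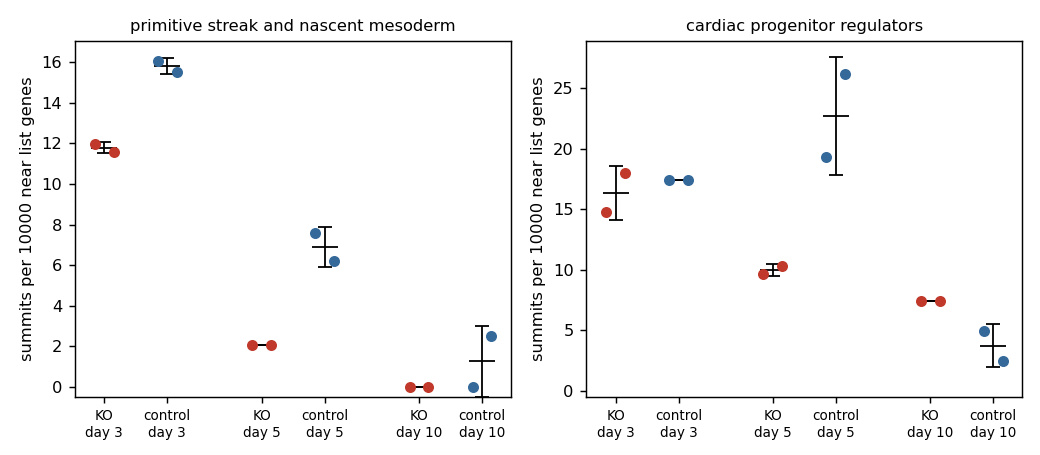
Summits per 10000 (vertical axis) assigned to the primitive streak and cardiac progenitor lists in each group (horizontal axis). Points are libraries (red KO, blue control), with the mean and SD (n = 2); streak values were 11.8 against 15.8 at day 3, and cardiac values 9.99 against 22.7 at day 5.

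The share of summits near gene ends did not differ over the days. KO minus control was −5.01 percentage points (two-sided exact permutation p = 0.222, adjusted p = 0.333), 0.695 for gene bodies (adjusted p = 0.556) and 4.32 elsewhere (adjusted p = 0.25). The gene-end difference came from day 10, where gene ends held 54.9% ± 3.28 of KO and 70.8% ± 2.76 of control summits (SD, n = 2). At that day the KO lists entered whole or nearly so and the Control lists only with their best ranks. Day 3 had 24.9% ± 0.167 and 24.7% ± 0.0635, and day 5 61.2% ± 0.959 and 60.6% ± 3.12, slightly higher in the KO in the mean. With all summits in place of N the gene-end difference was −10.3 and passed (exact permutation, adjusted p = 0.0417). Gene-end shares fell with list length, however. At day 3 they were 68.7% (KO) and 68.4% (control) in the 4028 best-ranked summits of each library, against the 24.9% and 24.7% above at N of 53456. Full KO lists were longer than the control lists at day 5 and shorter at day 10. A genotype difference thus cannot be told apart from list length in the value with all summits.

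Regions called in 1 genotype over all days were no more numerous than some other splits of the libraries gave. At the common N of 4028, 5 regions were found in at least 5 of 6 KO and at most 1 of 6 control libraries, near Zfp788, Cryl1, Grpel2, Tcf4 and Mbd1, and 20 in the reverse, among them regions near Oip5, Vcp, Coa7, Gbf1 and Zfp808 (all chosen after their values were seen). Of 100 splits of the libraries within days, the real one included, 22 (the real one again counted) gave at least the real 25 regions, with a median of 17 and a highest count of 50 among the others. Leaving out a library, which loosens the rule, gave KO counts of 19 and 19 (KO day 3 replicates 1 and 2), 12 (KO day 5 replicate 1), 41 and 32 (KO day 10), 17 and 16 (iHA-Foxk1 day 3), 11 and 23 (iHA-Foxk1 day 5) and 19 and 19 (Control day 10). Control counts were 31 (KO day 3 replicate 2), 37 and 38 (KO day 5), 40 and 39 (KO day 10), 45 and 45 (iHA-Foxk1 day 3), 31 and 33 (iHA-Foxk1 day 5) and 45 and 48 (Control day 10).

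Between days 3 and 5, genotype-specific regions recurred in the same direction. At N of 14519, among 10728 regions tested at both days, 210 were KO-only at both (61.5 expected from independent lists) and 54 control-only at both (2.39 expected). Opposite calls numbered 5 (4.51 expected) and 13 (32.6 expected). No library is shared between the days. Of the 264 recurring regions, 250 had a summit of the other genotype, of any score, within 1 kb at day 3 or 5. The other 14 were all KO-only and included regions near Atp6v1h, Il17a, Trim30d, Trim5, Trim12a and Hprt. At Hprt, an enzyme of purine salvage (chromosome X, 52988078 to 53021660), every KO library of days 3 and 5 had a summit at the lower gene end, at position 52988082, 52988128, 52988096 or 52988129, within the first 22.5% of its list. None of the 4 iHA-Foxk1 libraries had a summit of any score within 20 kb of the gene, and neither had any of the day 10 libraries, KO included. In the KO libraries of days 3 and 5 the summit had ranks from 7070 to 11898, beyond the length of both day 10 KO lists (4028 and 4755 summits). Its absence at day 10 thus does not show a loss of the site. How the iHA-Foxk1 line was made is not given in the sources used here, so that a change of this locus made with that line is not excluded. Trim5 was chosen after its values were seen.

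Between days 3 and 5, the genotype with more day-specific regions depended on the setting for day 5. At the common N of 14519, 1557 regions were day 3-only and 1487 day 5-only in the KO (other splits 164 to 188), and 3408 and 2034 in the control (other splits 124 to 341). Day 5-only regions were more numerous in the KO than in the control with all summits (2693 against 1132), with N divided by 2 (1086 against 900) and with merging at 100 bp (1537 against 1255). Day 3-only regions were more numerous in the control under each of these settings (20508 against 8538, 1365 against 1177 and 3215 against 1683). In the controls, day 5-only regions included 10 of 27 near cardiac progenitor regulators, led by Hand1, Gata4, Hand2 and Gata5 (37% against 13.4% of other regions), and 4 of 5 near Hox genes (Hoxb1, Hoxd1, Hoxd10 and Hoxc6). Neither passed (adjusted p = 0.0957 for both, 108 two-sided Fisher's exact tests, 7 under 0.05 before adjustment and none after). Summits near the cardiac list were 13.1 ± 2.92 and 22.7 ± 4.87 per 10000 at days 3 and 5 in the control and 9.64 ± 0.974 and 9.99 ± 0.487 in the KO (SD, n = 2 each). The difference between genotypes in this contrast of days was −9.3 (two-sided exact permutation of genotype within days, p = 0.333, 36 arrangements). Haematopoietic, Hox and housekeeping lists were higher at day 5 by 4.82, 2.76 and 3.62 per 10000, each with the smallest exact permutation p of the design (0.0556, adjusted p = 0.333).

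Regions specific to a day in both genotypes numbered 572 for day 3 and 486 for day 5, against 117 and 56.6 expected from independent lists. Most of these calls rested on summits below the compared ranks: with absence judged on full lists 31 and 6 were left, and with absence within 1 kb 20 and 1. KO counts then fell from 1557 and 1487 to 122 and 108 with full lists and to 45 and 16 within 1 kb, and control counts from 3408 and 2034 to 2377 and 504 and to 2220 and 406. Opposite calls, against 46 and 144 expected, numbered 5 and 13. By definition these are the regions given above with opposite genotype calls at days 3 and 5, so that they are no separate observation. Best-ranked day 3-only regions of both genotypes lay near Snph, Hacd1, Niban1, Scgb2b17 and Ankrd9, and day 5-only ones near Mid1, Hacd1, Ankrd9, Brf2 and Clcn4, with Hacd1 and Ankrd9 in both. In the KO alone, Col19a1, Mid1, Sp4 and Mgat1 led both directions. The control counts depended on iHA-Foxk1 day 5 replicate 1, the shortest list: without it, and with N raised to 34040, they were 11064 day 3-only and 14034 day 5-only, against 3264 and 2693 in the KO, and 1244 and 928 in both genotypes. Without KO day 5 replicate 2, 880 regions were day 3-only in both genotypes. Day 5-only control regions numbered 6277 without iHA-Foxk1 day 5 replicate 2. KO counts without KO day 3 replicate 1 or 2 were 2526 and 2539 day 3-only (2248 day 5-only without replicate 2), and without KO day 5 replicate 1 or 2 they were 2385 and 2553 day 5-only.

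Day 10 was set against the earlier days by counts of regions, with no test over libraries. Of 2377 reproducible regions at N of 4028, 348 were found in all 4 day 10 libraries and none of the 8 earlier ones, and 83 in the reverse. The best-ranked day 10-only regions lay between genes near Abcb11, Pak3, Rfc3, Chst2 and Stt3b, and early-only regions at the ends of Agbl4, Lrif1, Zfp551, Rab38 and Dcun1d5. No list passed in 36 two-sided Fisher's exact tests, and 1 was under 0.05 before adjustment: both endothelial regions, near Flt1 and Erg, were day 10-only (p = 0.0214, adjusted p = 0.77). Without iHA-Foxk1 day 5 replicate 1 there were 145 early-only regions, and with N divided by 2 there were 44.

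No chromosome differed in its share of summits after adjustment over 20 chromosomes. These shares were taken over full lists, which differed in length between the genotypes, most at days 5 and 10. With the N highest-scoring summits of each day, 0 chromosomes passed as well. KO minus control was −0.537 percentage points for chromosome 2 and 0.333 for chromosome 5 (exact two-sided permutation p = 0.00926 for both, adjusted p = 0.0926), and 0.413 for chromosome 8 (p = 0.0185, adjusted p = 0.123, same exact test). These 3 were under 0.05 before adjustment. Chromosomes 2 and 5 had the smallest p the design allows, which in 1 chromosome alone would have given an adjusted 0.185, so that 1 or 2 chromosomes alone could not pass. Without iHA-Foxk1 day 5 replicate 2, chromosomes 2, 5, 8 and 10 passed (exact permutation, adjusted p = 0.0463 each).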

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

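Tests of differences between days, summit shifts, delay, the short control list, low KO ranks, another day, opposite calls, gene ends and chromosome Y were chosen after the results were seen. Tests of neighbouring regions, of summit positions at both days and of chromosomes were set out before their values were known.

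Day 3 control-only regions near streak genes Mixl1, Gsc, Aplnr and Snai1 were weighed first. Summit shifts inside wide peaks were argued against, since the odds ratio was 3.7 (Fisher's exact test, adjusted p = 0.000997) when any KO summit within 1 kb ruled a region out. Loss of DNA around the genes in the KO line was argued against too: of 225 regions of other genes within 250 kb, 8% were control-only (exact 95% interval 4.81 to 12.3), against 9.59% over the genome, and the 25 regions lay on 11 chromosomes. As a biological alternative, a delay in which the KO opens these regions by its next sample cannot be told apart from a lasting difference: 4% (1 of 25, exact 95% interval 0.101 to 20.4) had a summit in both libraries labelled KO day 5, but the control itself kept only 2 and 8 of the 25 in its day 5 libraries, the share for other control-only regions was 7.46%, and these KO lists carry the tag D7. A passage between the sampled days, and a difference between the lines unrelated to Foxk1, remain open.

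Day 5 control-only regions near cardiac regulators Hand1, Gata6, Fgf10 and Isl1 were weighed second. The short list of control replicate 1 as whole source cannot be told apart from a genotype difference: without it the odds ratio was 2.46 in place of 10.8, still past the threshold (Fisher's exact test, adjusted p = 0.00175) but from a control arm of 1 library and more compared summits, and with both libraries kept the call ended with all summits and with N divided by 2 (adjusted p = 0.135 and 0.734). Regions called in the KO below the compared ranks were argued against as whole source of the enrichment, since the odds ratio was 12.1 with absence judged on full lists (Fisher's exact test, adjusted p = 0.0316), although 66.7% of the regions (8 of 12, exact 95% interval 34.9 to 90.1) had a KO summit of some score, against 80.3% of other control-only regions, and only 4 regions near Hand1, Gata5 and Bmp2 had none. KO libraries of another day, as the D7 in their peak names could mean, cannot be told apart from genotype, since 0 control libraries carry that day. A genotype effect on cardiac regulators thus remains 1 of several open readings.

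Genotype-specific regions recurring at days 3 and 5 were weighed last, and borderline peaks missed by chance were argued against, since opposite calls were at most 1.11 times their chance number while like calls were at least 3.41 times theirs. Of the recurring regions, 94.7% (250 of 264, exact 95% interval 91.3 to 97.1) had a summit of the other genotype within 1 kb, counted at any score. Summit positions that differ between the lines inside one peak thus cannot be told apart from summits below the compared ranks, since the count takes both. A change in copy number of a whole chromosome was argued against as the main source, since no chromosome with at least 10 recurring regions held over 1.72 times its share of tested regions. KO-only and control-only regions were pooled in this count, so that a smaller contribution of a chromosome cannot be told from it. A genome difference between the KO and control lines cannot be told apart from a Foxk1 effect, since genotype and line coincide: of 6474 gene ends open in all 4 KO libraries, 4 had no control summit within 1 kb (Hprt, Trim5, Trim12a and Gm51464), while in the other direction it was 0 of 5347.

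Several differences between the genotypes ran in opposite directions at 2 days at the N of each day, with no overlap of the libraries. Differences between days were not tested for these values, since N differed, and were tested at a common N, where no p under 0.0556 is possible (36 arrangements). Near Hox genes KO minus control was 4.68 summits per 10000 at day 3 and −4.82 at day 5, a difference of 9.5. Pluripotency genes had 1.22 and −4.48 at these days (difference 5.69). Fibroblast (feeder) genes had 0.842 and −3.44 (difference 4.29). At the N common to days 3 and 5 the opposite directions of these 3 lists were gone: KO minus control at day 3 was −0.689 for Hox, −0.344 for pluripotency and −0.344 for fibroblast genes. These means were lower in the KO as at day 5, but each difference was smaller than the SD of the control at day 3 (0.974, 0.974 and 0.487). Day 5 minus day 3 of the genotype difference was then −4.13 for Hox, −4.13 for pluripotency and −3.1 for fibroblast genes (two-sided exact permutation p = 0.333, 0.278 and 0.333). Cardiac progenitor regulators had −12.7 at day 5 and 3.72 at day 10 (difference −16.5), and −3.72 and 3.72 at the N common to all days (two-sided exact permutation p = 0.0556). At that N a summit counts as 2.48 per 10000, so that these differences rest on very few summits. Cell cycle genes had 0.468 at day 3 and −6.21 at day 10 (difference 6.67), but −3.72 and −6.21 at the N common to all days, lower in the KO at both (exact permutation p = 0.722). Gene-end shares differed by 0.232 points at day 3 and −15.9 at day 10 (difference 16.1), and by 0.385 and −15.9 at the common N, where the day 3 libraries overlapped (exact permutation p = 0.111). Gene-body shares differed by −2.52 at day 5 and 4.82 at day 10 (difference −7.33), and by −0.993 and 4.82 at the common N (exact permutation p = 0.0556). Both day 10 contrasts are open to the difference in list length at that day. The log10 number of summits differed by 0.308 at day 5 and −0.316 at day 10 (difference 0.623, exact permutation p = 0.0556).

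Chromosome Y, which the comparisons left out, held a larger share of summits in every KO library than in the controls of its day. Shares were 0.417% ± 0.0128 and 0.323% ± 0.00909 at day 3, 0.34% ± 0.00565 and 0.132% ± 0.012 at day 5, and 0.823% ± 0.0153 and 0.449% ± 0.0349 at day 10 (SD, n = 2). The mean difference was 0.225 points (two-sided exact permutation p = 0.00926, the smallest the design allows). Shares were taken over full lists of unequal length. Summits on Y numbered 242 and 229 (KO) against 170 and 179 at day 3, and 167 and 142 against 18 and 48 at day 5. At day 10 they numbered 33 and 40 in the KO and 45 and 37 in the Control libraries, so that the larger share there went with shorter KO lists.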

How the results depend on the processing

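Absence within 1 kb, odds ratios of lists under other merging, bins and absence rules, and leaving out libraries for chromosomes and for day 10 against earlier days, were added after the data were seen. No setting brought a list past the threshold by permutation over libraries, which was close to fixed by the design, since 1 list alone could not pass (smallest adjusted p 0.167). Unknown read depth and 2 libraries per group limit all counts; motif alternatives were not run. Replicate numbers did not pair the libraries (correlations of deviations 1.54e-08, −0.0218 and −0.0113 at days 3, 5 and 10), and the replicate block gave 0.00366 for the log10 summit number, −5.01 for gene ends and 0 lists and 0 chromosomes passing, with region counts equal by construction. Its smallest exact permutation p was 0.0312, so that 1 list, chromosome or annotation class alone could not pass (adjusted 0.562, 0.625 and 0.0938), whatever the data.

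Changes of region counts with list length follow from the construction of a setting. The gene-end difference with all summits is open to list length as well. The cause of the other changes, those of odds ratios among them, was not tested. With all summits, KO-only and control-only regions numbered 12889 and 700 at day 5 and 111 and 2359 at day 10, 1 list test passed, the cardiac odds ratio was 4.64, the gene-end difference −10.3, and 9 KO regions recurred over all days. Day 3-only and day 5-only regions were then 8538 and 2693 (KO), 20508 and 1132 (control) and 3061 and 160 (both). With N divided by 2, regions numbered 2520 and 2512 (day 3), 364 and 315 (day 5) and 239 and 237 (day 10). The 1 list test that passed then was neither the streak test of day 3 nor the cardiac test of day 5 for control-only regions. Their odds ratios were 2.3 and 8.58 (Fisher's exact test, adjusted p = 0.735 and 0.734). Control regions recurring over all days were then 5, control day 3-only and day 5-only regions 1365 and 900, and early-only regions 44. With absence judged on full lists, regions numbered 1053 and 225 (day 5) and 88 (day 10, KO-only), and day 3-only and day 5-only regions 122 and 108 (KO), 504 (control, day 5) and 31 and 6 (both). With absence within 1 kb they were 940 and 166, 41, then 45 and 16 (KO), 2220 and 406 (control) and 20 and 1 (both). Merging at 100 bp gave 1255 control and 271 common day 5-only regions. Calls of named genes held in 144 (full lists), 112 (absence within 1 kb), 148 (all summits), 45 (N divided by 2), 148 (100 bp), 173 (500 bp) and 165 (bins) of 188 cases, and in 36 of 52 without iHA-Foxk1 day 5 replicate 1.

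With 1 library left out, the rule is looser by construction, and where that library had the shortest list, N rose as well (from 14519 to 34040 without iHA-Foxk1 day 5 replicate 1, from 4028 to 4755 without KO day 10 replicate 1), so that both choices changed at once. KO-only regions ranged from 8029 to 11294 (day 3), 2883 to 8500 (day 5) and 560 to 1312 (day 10), and control-only regions from 6967 to 12216, 1381 to 11737 and 821 to 1066. Day 3-only regions ranged from 1557 to 3264 (KO), 3408 to 11064 (control) and 593 to 1244 (both), and day 5-only regions from 1487 to 2693, 2034 to 14034 and 520 to 928. Early-only regions ranged from 84 to 145, day 10-only from 348 to 484, regions recurring over all days from 6 to 41 (KO) and 25 to 48 (control), list tests passing from 2 to 5 and chromosomes passing from 0 to 4. Odds ratios ranged from 2.64 to 3.49 (streak) and 2.46 to 11.4 (cardiac), gene-end differences from −5.79 to −4.28 and log10 summit differences from −0.058 to 0.0653.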

Other observations

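The list tests without 1 gene and the count of splits were chosen after the results were seen, and the test of a slower change before its values were known.

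Beyond the best-ranked names, 10 more streak genes had control-only regions at day 3: Mesp1, a factor of early cardiac mesoderm, Lhx1, Evx1, Fgf8, Eomes, Tbx6, Dll1, Wnt3, Pdgfra and Nodal (chosen after their values were seen). Eomes, a T-box factor of the streak, had 3 such regions between 21531 and 93403 bp from the gene, and Mesp1 had 2 at 2741 and 3726 bp. Leaving out Gsc, the gene whose removal lowered the odds ratio of the streak list most, left it at 3.57, and leaving out Hand1 left that of the cardiac list at day 5 at 8.07.

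Whether the smaller number of day-specific regions in the KO at the common N reflected a slower change from day 3 to day 5 could not be decided. Shares of regions kept at day 5 were compared, but the control lost more day 3 regions (3408) than the KO (1557), so that the KO had to keep more of those lost by the other genotype. Of 1968 control day 3-only regions also found in both KO day 3 libraries, KO day 5 libraries kept 57.4% on average, and of 667 KO day 3-only regions found in both control day 3 libraries, control day 5 libraries kept 8.77%. Without iHA-Foxk1 day 5 replicate 1 the shares were 72.9% of 7137 and 15.8% of 1491, a difference of 57.2 points (48.6 with all libraries). A slower change in the KO and a lower yield of the control day 5 libraries, whose lists were shorter, cannot be told apart.

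For the regions that recurred over all days in 6 against 6 libraries, chance could not be excluded. Of the 100 splits used (of 108 possible within days), 22 gave at least the real 25 regions, the real split being counted in both numbers. The highest other split gave 50.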
